A study of Homo sapiens with 9 samples.

How the data were processed

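Lymphocytes were sorted by flow cytometry from human tumors and healthy tissue after digestion with collagenase and DNase, and libraries were made with the 10x Genomics 3' V3.0 kit, per the labels' protocols. The 9 libraries were 2 single-patient colorectal tumors, 2 single-patient endometrial tumors, a pool of healthy endometrium from both endometrial patients, and 4 pools of colorectal patients 3 to 6: healthy colon, and tumor cells sorted as gamma-delta T cells, as NK and T cells and as MAIT cells. The deposited matrices hold raw UMI counts per gene and cell barcode, per the file headers. Cell Ranger 2.1.1, Seurat and the genome build GRCh38 are named without a role, per the submitters' processing notes. In 5 libraries rows for hashtag antibodies stand beside the genes and were left out of the gene totals.

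The libraries held 14629 barcodes, 1069636 to 12782438 gene UMIs each and medians of 637 to 2426 genes per barcode. The 2 single-patient colorectal files list 33694 genes and the others 33538, so all steps used the 32889 genes that all libraries share, without XIST, TSIX and Y-linked genes. Cells needed at least 400 genes and at most 15% mitochondrial UMIs, which left 12478. Scrublet as run in scanpy 1.11.5 was applied to each library with 20 components and removed 73 cells (0.585%), which left 12405. Median depth in the cells used was 1944 and 1886 UMIs in the colorectal tumor libraries, 5752 and 6349 in the endometrial tumor libraries and 6688 in healthy endometrium. It was 1581 in the gamma-delta T sort, 7241 in the NK and T sort, 8279 in the MAIT sort and 8529 in healthy colon. A gene absent from a cell in the 3 shallow libraries can therefore be present below detection.

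All cells were clustered together on 2000 variable genes, 30 principal components and 15 neighbours (scikit-learn 1.9.0) with Leiden clustering (leidenalg 0.10.2) at resolution 2 and seed 1. T-cell receptor, immunoglobulin, mitochondrial, ribosomal and heat shock genes were kept out of the variable genes. Clusters were named from fixed markers, and the resolution and the marker levels that decide a name were set while the clusters were inspected. The 38 clusters gave 10 NK-like, 7 CD8 T-like, 6 CD4 T-like, 3 MAIT-like and 1 each of Treg-like, proliferating, epithelial, myeloid, ILC3-like, plasma and B-like, and 5 stayed unnamed. The naming rules held no class for gamma-delta T cells, so these cells can sit within other classes.

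For tested comparisons UMI counts were summed per library and class with at least 20 cells. edgeR 4.0.16 fitted the sums with quasi-likelihood tests, TMM factors and filterByExpr, at a Benjamini-Hochberg adjusted p of 0.05. Tumor against healthy was fitted with tissue as covariate in NK-like, CD8 T-like, CD4 T-like and Treg-like cells. Colorectal against endometrial tumor was fitted in NK-like cells, and the difference of the tumor-healthy effect between tissues in NK-like and CD8 T-like cells. Other classes, with 20 cells in fewer libraries, were not tested. Gene lists for tissue residency, circulation and egress, cytotoxic granules, checkpoint, NK receptors, cytokines and chemokines, type 17, transcription factors, interferon, proliferation, stress, hypoxia, TGF-beta, class II and uterine NK cells were fixed beforehand, with lists of epithelial, stromal, myeloid, B and plasma and red cell genes. They were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with the correlation estimated per list, and each list's genes were also adjusted over the list alone. DESeq2 1.42.0 was run on the same sums. Shares of cells were compared by an exact permutation test.

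Comparisons of 1 library with 1 were not tested. CPM carry exact Poisson intervals, ratios exact conditional binomial intervals and shares Clopper-Pearson intervals, all at 95% and for counting error only. Median log2 ratios used list genes with at least 10 UMIs and were placed among 10000 random lists drawn from the 100 genes nearest in expression. A gene at 0 on one side was set against 3 counts. After the data were seen, the cells that carry each named gene were counted, since the intervals treat UMIs of 1 cell as independent. Genes were named if they were list members or, in these comparisons, if they had at least 30 UMIs, at least 50 CPM and a ratio of at least 2, and were among the 10 per direction with the interval furthest from 1. Beyond the lists, receptor and immunoglobulin variable segments, most HLA and KIR genes, some genes with common germline deletions, and mitochondrial and ribosomal genes were not named. KLRC2, which some people lack, was named as a list member. No gene passed in a tested comparison, so only list members are named there.

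Scripts were tested on simulated counts with 200 changed genes per run. For tumor against healthy in NK-like cells edgeR ran on 9484 genes and recovered 4.69% of 2-fold, 44.6% of 4-fold and 93.2% of 8-fold changes. In CD4 T-like cells it ran on 8904 genes and recovered 13.1%, 77.0% and 95.2% of the same sizes. In CD8 T-like cells it ran on 9202 genes and recovered 4.69%, 50.8% and 88.9%, and in Treg-like cells on 5232 genes 8.20%, 82.0% and 93.1%. For colorectal against endometrial tumor in NK-like cells it ran on 10151 genes and recovered 1.56%, 35.9% and 78.5%. For the NK-like tissue difference it recovered 0 of 66 genes at 8-fold among 10209 genes run, and for the CD8 T-like tissue difference 25.0% among 9970. False calls numbered 4 in NK-like, 19 in CD8 T-like, 12 in CD4 T-like and 8 in Treg-like cells between tumor and healthy, 1 between the cancers, and 0 and 13 for the NK-like and CD8 T-like tissue differences. For the NK-like ratio to healthy colon, the intervals held the true ratio for 96.1% of 10771 genes and 198 of 200 genes changed 4-fold passed the ratio rule.

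Alternatives covered other normalization, DESeq2, no filter on low counts, other cell filters, doublets kept, and classes from clustering each library alone. They also covered donor set or replicate as a block, and immunoglobulin, hemoglobin, mitochondrial and ribosomal protein genes left out before scaling. Each library was also left out in turn. Doublets by hashtag, a finer clustering, fits without both single-patient colorectal libraries and list tests of the tissue difference with an estimated correlation were added after seeing the data. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3.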

Results

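Lymphocytes sorted from colorectal and endometrial tumors, and from healthy colon and endometrium, were compared by cell class in 9 single-cell libraries. The classes tested gene by gene were NK-like cells and T cells of the CD8, CD4 and Treg types. NK-like clusters were named by TYROBP and FCER1G against CD3D and CD3G, and KLRF1 was not required. The NK-like class also held cells with CD3 transcripts, which made up 79.6% of it in healthy colon. MAIT-like cells, marked by SLC4A10, KLRB1 and NCR3, and ILC3-like cells, marked by KIT and LST1, were described without such a test. Levels are given as CPM (counts scaled to the UMIs of the class or library). Groups, main tests, gene lists and most alternatives were chosen before the data were examined.

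NK-like cells were present in all 4 single-patient tumor libraries, while cells of the named CD8 T-like and CD4 T-like clusters were common in the endometrial tumors and few in the colorectal ones, where many T cells stayed in unnamed clusters. NK-like cells made up 12.4% of colorectal tumor library 1 (95% Clopper-Pearson interval 11.5 to 13.4), 55.7% of colorectal tumor library 2 (52.9 to 58.5), 29.4% of endometrial tumor library 1 (27.3 to 31.5) and 49.8% of endometrial tumor library 2 (46.7 to 52.8). CD8 T-like cells averaged 32.8% of the endometrial tumor libraries (SD 9.83, n = 2) and 0.144% of the colorectal tumor libraries (SD 0.142, n = 2). The colorectal mean was 6.11% with doublet calls kept and 6.14% with libraries clustered on their own. The mean of 0.144% leaves out cluster 27, with 139 cells of colorectal tumor library 2. Over all its cells, cluster 27 measured CD3D at 2366, CD8A at 756 and CD8B at 343 CPM. It stayed unnamed because its top genes held more NK markers. Unnamed cells averaged 41.0% of the colorectal libraries, against 35.7% with doublet calls kept and 40.8% with libraries clustered on their own. The low CD8 T-like mean therefore depends on how clusters were named. CD4 T-like cells averaged 15.1% (SD 0.921) and 0.361% (SD 0.416), and Treg-like cells 6.18% (SD 0.651) and 3.15% (SD 4.46), in the same order. MAIT-like cells averaged 13.4% of the colorectal (SD 7.25) and 2.13% of the endometrial tumor libraries (SD 1.25). At a raised clustering resolution the colorectal MAIT-like mean was 9.45% (SD 12.6), with p = 1.0 by the exact permutation test. The exact permutation test gave p = 0.333 for the CD8, CD4 and MAIT-like shares, the smallest p that 2 libraries against 2 can give, p = 0.667 for Treg-like and p = 1.0 for NK-like cells. The healthy endometrium pool held 37.5% CD8 T-like and 30.2% CD4 T-like cells and 11.6% NK-like cells, and the healthy colon pool 49.3% CD4 T-like, 16.3% NK-like and 15.4% CD8 T-like cells. Of 38 clusters, 5 stayed unnamed, and 3114 of their 3368 cells came from colorectal tumor library 1. Clusters 0, 1 and 4 met no class. Clusters 27 and 35 met the CD8 T-like and CD4 T-like marker levels. They lost the name because their top genes held more NK and B markers. The largest of the 5 unnamed clusters were led by MAL and LEF1, genes of naive-type T cells, and by GZMH and GNLY. The cluster led by GZMH and GNLY held 622 cells of colorectal tumor library 1. Over all its cells TYROBP measured 1159 CPM, KLRF1 452 and CD3D 463, so it carried both NK and T-cell markers. The interval of the NK-like share of that library covers counting error and not the naming of this cluster. The cells were sorted before sequencing, so these shares describe what was sequenced and need not match the tissue.

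**Figure D1:**
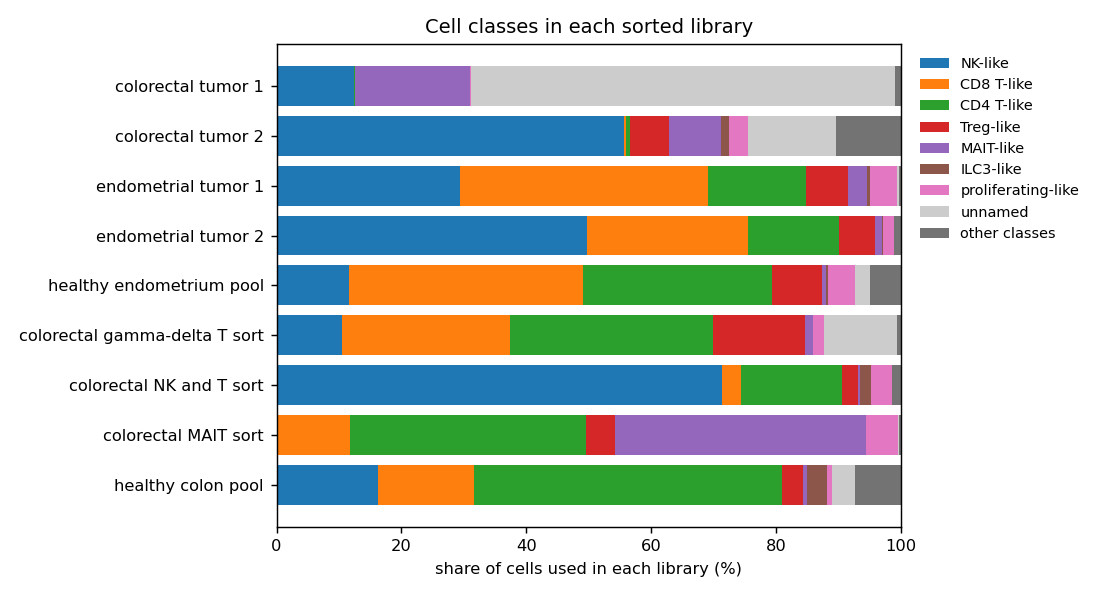
Share of each cell class among the cells used in each of the 9 libraries. The 3 colorectal sorts and the healthy colon pool hold cells of 4 patients each, and the healthy endometrium pool holds cells of both endometrial patients.

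NK-like cells of tumors carried more class II and cytotoxic transcripts and less stress, glycolysis and proliferation transcripts than NK-like cells of healthy tissue, with no single gene past the test over all genes. None of the 5 list calls held with an estimated correlation. HLA-DRA, a class II chain that activated lymphocytes express, was the only class II gene that rose when adjusted over the list alone, by 2.25 (SE 0.40) on the log2 scale. HLA-DPB1 was higher by 1.17 (SE 0.46) and CD74 by 1.23 (SE 0.60), and of the 9 class II and activation genes measured 1 rose, 0 fell and 8 did not pass. Among the cytotoxic granule genes 12 of 13 were higher in tumors, with GZMK at 1.18 (SE 0.48), GZMH at 1.35 (SE 0.89) and GNLY at 0.86 (SE 0.68), and 0 rose or fell. GNLY was -0.20 without healthy colon. ZNF683, a residency transcription factor, was higher by 3.05 (SE 0.90) and CXCR6, a homing receptor of resident cells, by 1.98 (SE 0.95). The residency list as a whole was split, with 5 of 10 genes higher. BHLHE40 was higher by 1.23 (SE 0.46), the inhibitory receptor gene KLRC1 by 1.05 (SE 0.42) and the interferon-induced GBP5 by 0.96 (SE 0.37). SPINK2, listed for uterine NK cells, fell by 1.34 (SE 0.28) when adjusted over its list alone, where 0 rose and 7 did not pass. VEGFA was lower in tumors at -1.30 (SE 0.50), 13 of 15 hypoxia and glycolysis genes were lower, and 17 of 20 stress and heat shock genes and 8 of 9 proliferation genes were lower.

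Camera placed the cytotoxic list up (adjusted p = 0.00401 with the preset correlation, adjusted p = 0.772 with an estimated correlation). The class II list was up (adjusted p = 0.00533, and adjusted p = 0.605 with an estimated correlation). The stress list was down (adjusted p = 0.00246, and adjusted p = 0.772 with an estimated correlation). The hypoxia list was down (adjusted p = 0.00401, and adjusted p = 0.772 with an estimated correlation), as was proliferation (adjusted p = 0.00922, and adjusted p = 0.772 with an estimated correlation). Median log2 fold changes were 0.50 for cytotoxic granule, 0.45 for class II, -0.47 for stress, -0.38 for hypoxia and -0.77 for proliferation genes. NK receptors and adaptors were higher for 7 of 17 genes and cytokines and chemokines for 10 of 17, and the circulation list for 8 of 9 (median 0.44, adjusted p = 0.105, and adjusted p = 0.804 with an estimated correlation). HBA1, a red cell gene, had 317 UMIs in NK-like cells of the tumor libraries and 0 in those of healthy tissue, an at least 14.4-fold difference against 3 counts, and HBA1 rose adjusted over the red cell list alone. Over all cells of the single-patient colorectal libraries HBA1 had 126 and 62 UMIs, but the red cell gene HBB had 0 in both. HBA1 was also higher in these libraries than in the endometrial tumors, and their files list other genes. The HBA1 difference therefore need not be one of tumor against healthy tissue. The other-cell lists of stroma, myeloid cells and epithelium had 2, 1 and 1 genes above the filter and called none. edgeR called 0 of 9681 genes at an adjusted p under 0.05, with 196 at an unadjusted p under 0.05. DESeq2 called 2 genes and edgeR without the low-count filter 15. Cells with a CD3D, CD3E or CD3G UMI made up 79.6% of the NK-like class in healthy colon, 41.7% in healthy endometrium and 15.1% to 57.2% in the tumor libraries. TRAC was found in 77.7% of the healthy colon cells of the class. These shares of cells with a UMI are at unequal depth, with library medians of 8529 UMIs in healthy colon and 1944 in colorectal tumor library 1. Cluster 16, led by CD160 and ID3, held most healthy colon cells of the class, and clusters high in FGFBP2 held 12.1% of them, against 60.4% in healthy endometrium, 75.9% and 60.5% in the colorectal and 5.13% and 62.1% in the endometrial tumor libraries, and 43.1% in the colorectal sort.

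CD8 T-like cells of tumors carried more transcription factor and fewer NK receptor transcripts than those of healthy tissue, in 2 endometrial tumors and the pooled colorectal tumor sort. Neither list call held with an estimated correlation. With the preset correlation 5 lists were called with at least 200 genes and at most 25% mitochondrial UMIs and 1 with doublet calls kept. The count also moved with each library left out. EOMES, a transcription factor of effector CD8 T cells, rose by 1.93 (SE 0.38) when adjusted over its list alone, and BHLHE40 was higher by 0.84 (SE 0.26) without passing. CCL3, a chemokine for monocytes and T cells, rose by 2.04 (SE 0.36) adjusted over its list alone, with CCL4 at 1.07 (SE 0.39). IL17A rose by 5.70 (SE 1.27) adjusted over its list alone, but measured 346 CPM in the colorectal sort and 15.6 and 0.563 in the endometrial tumors. GZMK was higher by 0.90 (SE 0.25), GZMH by 0.71 (SE 0.29), GBP5 by 0.85 (SE 0.24) and OASL by 0.82 (SE 0.26), without passing. KLRB1 was lower at -0.88 (SE 0.29), KLRC2 at -1.77 (SE 0.83) and IL2RA at -3.22 (SE 0.98). KLRC2 was 0.20 without healthy endometrium, IL2RA 0.11 and GZMK -0.15 with libraries clustered on their own, and GZMK -0.39 with doublet calls kept. The transcription factor list had 13 of 18 genes higher (median 0.29, camera adjusted p = 0.00524, and adjusted p = 0.62 with an estimated correlation). The NK receptor list had 5 of 16 genes higher (median -0.52, camera down with adjusted p = 0.00524, and adjusted p = 0.62 with an estimated correlation). Checkpoint genes were split, with 9 of 15 higher, and so were residency genes, with 5 of 11 higher. edgeR called 0 of 9544 genes, with 191 at an unadjusted p under 0.05, DESeq2 called 2, and edgeR without the low-count filter 49. The class came from clusters 10 and 22, led by CXCL13 and CD8B, in endometrial tumor library 1. It came from clusters 24 and 13, led by GZMH and GZMK, in endometrial tumor library 2, from cluster 14 in healthy endometrium and cluster 31 in healthy colon.

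CD4 T-like cells showed the widest tumor difference. Their tumor cells carried more transcripts for cytokines and chemokines, the type 17 programme, cytotoxic granules and tissue residency, and less S1PR1 and KLF3, but none of the list calls held with an estimated correlation. CSF1, a macrophage growth factor, rose by 3.57 (SE 0.35), XCL2 by 4.73 (SE 0.50), CCL5 by 2.19 (SE 0.27), IFNG by 2.95 (SE 0.44), CCL4 by 3.42 (SE 0.57), CCL3 by 4.54 (SE 0.82) and CCL20 by 3.36 (SE 0.62), all adjusted over the list alone. Of 19 cytokine and chemokine genes measured, 11 rose that way, 0 fell and 8 did not pass. CSF1 measured 51.9 and 35.9 CPM in the endometrial tumors against 3.66 in healthy endometrium, and 79.3 in the colorectal sort against 4.30 in healthy colon. In the type 17 list 9 of 10 genes rose adjusted over the list alone, among them AHR by 1.55 (SE 0.27), CCR6 by 1.73 (SE 0.46) and IL4I1 by 2.58 (SE 0.68). IL17A rose by 7.82 (SE 1.30) adjusted over its list alone, with 1265 CPM in the colorectal sort, 28.5 and 2.23 in the endometrial tumors, and 3.11 and 0.523 in the healthy pools. CXCR6 rose by 3.53 (SE 0.68), ITGA1 by 1.87 (SE 0.44), ITGAE by 1.47 (SE 0.35) and PRDM1 by 1.32 (SE 0.25) among 11 residency genes, of which 5 rose, 0 fell and 6 did not pass, adjusted over the list alone. Cytotoxic genes followed, with NKG7 up by 2.1 (SE 0.34), CST7 by 1.65 (SE 0.29), PRF1 by 1.85 (SE 0.36) and GNLY by 2.33 (SE 0.47). Of the 11 cytotoxic granule genes 7 rose, 0 fell and 4 did not pass, adjusted over the list alone.

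Checkpoint genes rose for 3 of 13 in the same CD4 T-like cells, adjusted over the list alone, including TNFRSF9 by 1.75 (SE 0.35) and PDCD1 by 1.59 (SE 0.39). ENTPD1 was higher by 1.74 (SE 0.58) and passed in the uterine NK list alone, where 3 of 6 rose. LDLRAD4 rose by 1.37 (SE 0.27) in the TGF-beta list, where 3 of 10 rose adjusted over the list alone, and SMAD7 was higher by 0.78 (SE 0.27) without passing. S1PR1, the receptor for egress from tissue, fell by 1.88 (SE 0.30) and KLF3 fell by 1.80 (SE 0.33), adjusted over the list alone, while KLF2 at -1.09 (SE 0.55) and CCR7 at -0.92 (SE 1.02) did not pass. CCR7 was 0.97 without the colorectal sort and also without healthy colon. Of 7 circulation genes 0 rose, 2 fell and 5 did not pass. ID2 rose by 1.82 (SE 0.29) and BATF by 1.63 (SE 0.30), adjusted over the list alone, and the naive-type factor LEF1 was lower at -1.69 (SE 0.55). ATF3, a stress gene, rose by 2.84 (SE 0.29), EPSTI1 by 1.03 (SE 0.24) and OASL by 1.33 (SE 0.32), adjusted over their lists alone, in lists with 18 of 20 stress and 20 of 22 interferon genes higher. IGKC, a plasma cell gene, rose by 3.51 (SE 0.49) adjusted over its list alone, and 2 of 3 B and plasma genes rose. AIF1, a myeloid gene, fell by 2.23 (SE 0.86) adjusted over its list alone, as its only measured member.

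Camera placed 12 of 16 lists past 0.05 in CD4 T-like cells with the preset correlation and 0 with an estimated correlation. Cytokines and chemokines had adjusted p = 2.66e-17 (median 2.24), and adjusted p = 0.127 with an estimated correlation. Type 17 had adjusted p = 1.83e-11 (median 2.74), and adjusted p = 0.172 with an estimated correlation. Residency had adjusted p = 1.75e-09 (median 1.32), and adjusted p = 0.127 with an estimated correlation. Circulation was down with adjusted p = 3.19e-05 (median -1.09), and adjusted p = 0.148 with an estimated correlation. edgeR called 0 of 9348 genes over all genes, with 1135 at an unadjusted p under 0.05, while DESeq2 called 100 and edgeR without the low-count filter 559. CCL3 was -0.28 with doublet calls kept, and PDCD1 was -0.57 and EPSTI1 -0.0024 with at least 200 genes and at most 25% mitochondrial UMIs, so the direction of these genes turned with the cells admitted. The colorectal sort's CD4 T-like cells came mostly from cluster 17, led by IL17A and IL22 (160 of 228 cells). The healthy colon cells came from cluster 12, led by CCR7 (285 of 475 cells), and cluster 18, led by PASK. The endometrial tumor cells came mostly from cluster 15 (143 of 283 and 117 of 152 cells), and those of healthy endometrium from cluster 23, led by MAL (195 of 251 cells), so the class held different clusters in tumor and healthy tissue.

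Treg-like cells of tumors carried more cytotoxic, stress and interferon transcripts and less LAG3 and IL10 than Treg-like cells of healthy tissue. None of the 3 list calls held with an estimated correlation. GZMA rose by 2.70 (SE 0.65) adjusted over its list alone, and GZMK had 69 UMIs in tumor cells and 0 in healthy cells, an at least 11.0-fold difference against 3 counts. Of 11 cytotoxic granule genes 2 rose, 0 fell and 9 did not pass, adjusted over the list alone. LAG3, an inhibitory receptor, fell by 1.98 (SE 0.46) and IL10, a suppressive cytokine, fell by 2.88 (SE 0.72), each adjusted over its list alone. PFKFB3, a glycolysis regulator, rose by 1.61 (SE 0.38) adjusted over its list alone. TNFSF14 was higher by 2.82 (SE 1.03), OASL by 1.23 (SE 0.44) and ATF3 by 1.41 (SE 0.69), and CCR7 was lower at -1.52 (SE 0.68; 0.41 without healthy colon), without passing. Stress genes were higher for 19 of 20 (median 0.63, camera adjusted p = 0.00586, and adjusted p = 0.552 with an estimated correlation). Interferon genes were higher for 15 of 17 (median 0.26, camera adjusted p = 0.0079, and adjusted p = 0.552 with an estimated correlation). The cytotoxic list had a median of 0.39 (camera adjusted p = 0.000175, and adjusted p = 0.552 with an estimated correlation). edgeR called 0 of 5460 genes, with 139 at an unadjusted p under 0.05, DESeq2 called 0, and edgeR without the low-count filter 23. The labels do not say how separately the samples were processed, so p-values here measure the spread between these libraries, and each healthy tissue was 1 pooled library.

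**Figure D2:**
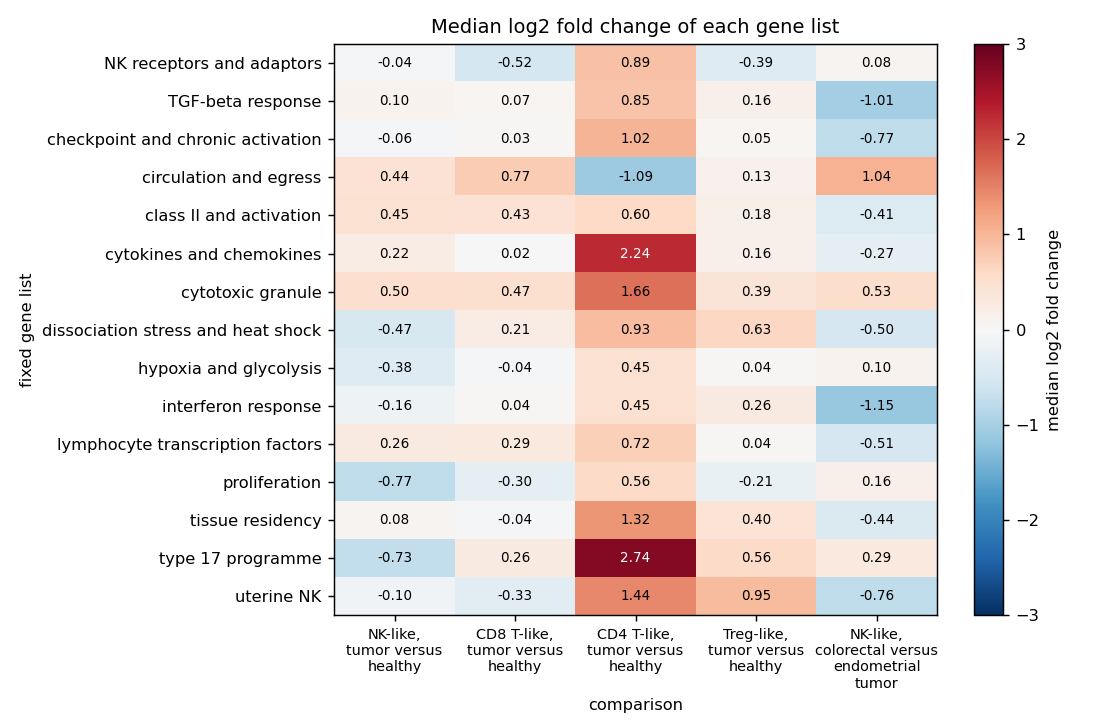
Median log2 fold change of the measured genes of each fixed list in the 5 tested comparisons other than the tissue differences, from edgeR fits of UMI sums per library and class. Positive values are higher in tumors, or in colorectal tumors for the last column.

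NK-like cells of colorectal tumors carried fewer interferon, residency, checkpoint and TGF-beta response transcripts and more circulation transcripts than those of endometrial tumors. None of the 8 list calls held with an estimated correlation. Without the low-count filter 1 list was called, and the count also moved with each single-patient tumor library left out. IFIT3 fell by 1.98 (SE 0.36), GBP5 fell by 1.65 (SE 0.30), XAF1 fell by 1.44 (SE 0.30), MX1 fell by 1.32 (SE 0.31) and IFIT1 fell by 2.80 (SE 0.72), adjusted over the list alone. Of 22 interferon genes 0 rose, 9 fell and 13 did not pass. PRDM1 fell by 2.05 (SE 0.33), NFIL3 fell by 3.12 (SE 0.54), IKZF3 fell by 2.01 (SE 0.35) and EOMES, needed for NK maturation, fell by 1.67 (SE 0.45), the 4 transcription factors of 18 that passed over the list alone. CXCR6 was lower at -2.91 (SE 0.90) and ITGA1, a collagen-binding integrin of resident cells, at -2.27 (SE 0.94), without passing. SKI fell by 1.61 (SE 0.35) in the TGF-beta list, adjusted over the list alone, with SMAD7 at -1.07 (SE 0.30) and PMEPA1 at -2.29 (SE 0.70). LAG3 was lower at -1.16 (SE 0.51), and all 15 checkpoint genes were lower. CCR7, a lymph node homing receptor, rose by 1.76 (SE 0.43), while KLF2 fell by 2.06 (SE 0.51), adjusted over the circulation list alone. KLF3 at 1.73 (SE 0.72) and S1PR5 at 2.18 (SE 0.92) did not pass, nor did KLRF1 at 1.5 (SE 0.65), KLRK1 at -2.11 (SE 0.48) or XCL2 at -2.28 (SE 0.58).

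Camera placed the interferon list down between the NK-like cells of the cancers (median -1.15, adjusted p = 5.01e-08, and adjusted p = 0.406 with an estimated correlation). TGF-beta response was down (median -1.01, adjusted p = 0.0026, and adjusted p = 0.606 with an estimated correlation), checkpoint was down (median -0.77, adjusted p = 0.00607, and adjusted p = 0.683 with an estimated correlation) and residency was down (median -0.44, adjusted p = 0.0128, and adjusted p = 0.606 with an estimated correlation). Circulation was up (median 1.04, adjusted p = 0.0331, and adjusted p = 0.683 with an estimated correlation). Colon epithelium genes were higher for 7 of 7 in the colorectal tumors (adjusted p = 0.00124, and adjusted p = 0.606 with an estimated correlation). Endometrial epithelium genes were higher for 4 of 4 (adjusted p = 0.0195, and adjusted p = 0.606 with an estimated correlation). Both epithelium lists hold EPCAM, KRT8, KRT18 and KRT19, so the endometrial list need not be a separate signal. The 1 myeloid gene measured rose, adjusted over its list alone. EPCAM had 22 UMIs in the colorectal and 0 in the endometrial NK-like cells, an at least 20.1-fold difference against 3 counts. HBA1 rose by 4.29 (SE 0.48) adjusted over the red cell list alone, although HBB had 0 UMIs over all cells of both single-patient colorectal libraries. JUND fell by 3.42 (SE 0.50) and ALDOA rose by 4.44 (SE 0.45), adjusted over their lists alone. JUND measured 185 and 347 CPM in the single-patient colorectal libraries and 3195 in the pooled colorectal sort. The single-patient colorectal files list 33694 genes and the other 7 libraries 33538, and their barcodes shared 444 starts with each other and 28 to 110 with the other libraries, although the labels name the same kit for all. Gene reference, kit and cancer type therefore cannot be separated in this comparison. The 2 colorectal libraries also differed from each other, with a residency median of -3.23 (-3.51 to -2.37) in NK-like cells of library 1 over library 2. edgeR called 0 of 10473 genes, with 1547 at an unadjusted p under 0.05, DESeq2 called 98, and edgeR without the low-count filter 723. It called 128 genes without endometrial tumor library 1, 343 without library 2 and 27 with at least 200 genes and at most 25% mitochondrial UMIs. Clusters 6 and 26 held the class in colorectal tumor library 1, clusters 9 and 19 in colorectal tumor library 2, cluster 3 in endometrial tumor library 1, and clusters 11 and 3 in endometrial tumor library 2.

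The tumor-healthy difference of NK-like cells itself differed between the tissues in 8 lists, circulation and egress among them, with the preset correlation and in 0 with an estimated one. The interaction took the endometrial effect minus the colon effect, and all 9 circulation genes were negative, with a median of -4.55. CCR7 fell by 4.88 (SE 1.06), S1PR1 fell by 5.92 (SE 1.52), KLF3 fell by 4.90 (SE 1.52), S1PR5 fell by 4.93 (SE 1.82) and ITGB2 fell by 3.45 (SE 0.99), adjusted over the list alone. Healthy colon measured 0.639 CPM of S1PR1 (1 UMI) and the colorectal sort 13.8, whereas healthy endometrium measured 24.9 and the endometrial tumors 2.94 and 13.4. KLRC2, an activating receptor, rose by 3.17 (SE 0.65) in the interaction and KLRG1 fell by 3.05 (SE 0.76), adjusted over the list alone. LAG3 was positive at 3.53 (SE 1.04), TIGIT at 2.90 (SE 0.86) and ITGA1 at 5.42 (SE 1.87), while GZMB at -3.42 (SE 0.94), FCGR3A at -3.94 (SE 1.37), PRF1 at -2.38 (SE 0.89), GNLY at -2.46 (SE 1.00) and KLRF1 at -3.31 (SE 1.22) were negative, without passing. IFI44L fell by 5.28 (SE 1.08) adjusted over its list alone, with IFI44 at -3.47 (SE 0.98) and IFIT3 at -2.41 (SE 0.80). Camera placed circulation down with adjusted p = 4.3e-13, and adjusted p = 0.451 with an estimated correlation. edgeR called 0 of 10473 genes, with 489 at an unadjusted p under 0.05, DESeq2 called 2, and edgeR without the low-count filter 143. In CD8 T-like cells the same interaction put 14 of 15 checkpoint genes and 19 of 22 interferon genes below 0, with OAS1 lower by 4.94. That fit left 1 residual degree of freedom, since each group but the endometrial tumors was 1 library. It measures no spread within colon or within healthy tissue. There edgeR called 0 of 10431 genes with 448 at an unadjusted p under 0.05, DESeq2 called 0, and edgeR without the low-count filter 159. The NK-like classes differed in CD3 content, with a CD3 UMI in 79.6% of cells in healthy colon, 38.8% in the colorectal sort, 41.7% in healthy endometrium and 57.2% and 15.1% in the endometrial tumors.

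**Figure D3:**
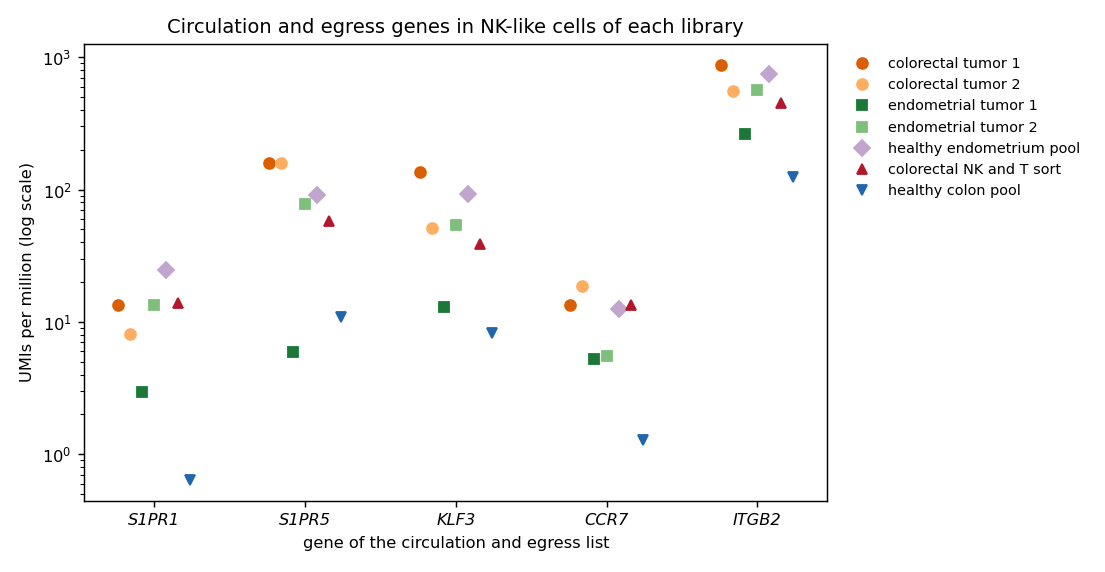
CPM of the circulation and egress genes named above in the summed NK-like cells of each library with at least 20 such cells, on a log scale. Each point is 1 library.

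Between the pooled colorectal tumor sort and healthy colon of the same 4 patients, NK-like cells carried more circulation, type 17, interferon and cytotoxic transcripts in the tumor sort. All 9 circulation genes were higher in the tumor sort, with a median log2 ratio of 2.38 (95% counting interval 1.92 to 2.81), above all 10000 random lists matched on expression (percentile 100). That median was 1.61 with at least 800 genes and at most 10% mitochondrial UMIs, 1.78 with doublet calls kept and 3.1 with libraries clustered on their own. KLF2, which drives S1PR1, was 8.53-fold higher (7.63 to 9.56). The NK maturation factor EOMES was 7.90-fold higher (5.32 to 12.3), ZNF683 26.7-fold (10.4 to 98.3) and SOX4 25-fold (12.1 to 62.5). FCGR3A, the receptor for antibody-coated cells, was 8.06-fold higher (6.38 to 10.3), FGFBP2 5.18-fold (4.41 to 6.14), MYOM2 9.04-fold (6.82 to 12.3), PTGDS 10.2-fold (6.67 to 16.6), CD82 11.8-fold (5.66 to 29.4) and RHOB 5.09-fold (4.44 to 5.85). Interferon genes were higher for 22 of 22 (median 1.26, 1.10 to 1.54), cytotoxic granule genes for 11 of 13 (median 0.95, 0.87 to 1.11) and type 17 genes for 8 of 11 (median 2.20, 1.55 to 2.89). Checkpoint genes were lower for 11 of 13 (median -0.39, -0.51 to -0.21, percentile 0.02), hypoxia genes for 12 of 15 (median -0.47, -0.56 to -0.39) and residency genes for 7 of 11 (median -0.22, -0.36 to -0.11, percentile 4.22). CD3D was 9.86-fold lower in the tumor sort, CD3G 8.69-fold, TRGC2 6.05-fold, CDH17 12.8-fold, ASB2 6.75-fold, KLHL23 4.92-fold, ADRB1 4.69-fold, HIC1 4.37-fold and RGS1, a residency gene, 3.55-fold. The labels give the tumor cells as an NK and T sort, apart from the gamma-delta T and MAIT sorts, and the healthy cells as 1 lymphocyte pool, so the gates can set such ratios. MT1G was 39.0-fold lower by UMIs, but all 86 UMIs of healthy colon were in 1 cell. B and plasma genes were higher for 6 of 9 (median 1.14, -0.08 to 2.81). The tumor cells came from clusters 5, 7 and 16 and the healthy cells mostly from cluster 16, and 79.6% of the healthy cells had a CD3 UMI against 38.8% of the tumor cells.

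CD4 T-like cells of the pooled tumor sort carried far more type 17 transcripts than those of healthy colon. IL17A measured 1265 CPM in the tumor sort and 3.11 in healthy colon, a 407-fold ratio (238 to 765). IL17F was 303-fold higher (53.6 to 12060), IL26 261-fold (71.6 to 2168) and CSF2 132-fold (50.8 to 487). CXCL13, a B-cell chemokine, had 357 UMIs in 12 tumor cells and 0 in healthy colon, at least 239-fold against 3 counts, with 45.4% of them in 1 cell. CXCL9 had 118 UMIs, all in 1 tumor cell, and 1 cell held 47.3% of the CSF2 UMIs. CXCR6 was 49.6-fold higher (35.9 to 70.6), ADAM12 142-fold (38.5 to 1181), and the heat shock genes HSPA6 67.8-fold (53.4 to 87.5) and SERPINH1 71.0-fold (39.3 to 144). All 13 type 17 genes were higher (median 3.50, 3.22 to 4.03), as were 16 of 18 cytokine genes (median 2.55, 2.47 to 2.80), 10 of 11 residency genes (median 1.81, 1.59 to 2.26), 13 of 14 checkpoint genes (median 2.11, 1.62 to 2.45) and 9 of 10 proliferation genes (median 3.09, 2.28 to 3.62). Circulation genes were lower for 6 of 7 (median -1.79, -1.89 to -1.52, percentile 0). AREG was 13.6-fold lower, PLAC8 8.44-fold, ACTN1 12.1-fold, CD27 8.45-fold, SCML1 12.1-fold, ZBTB10 8.87-fold, YBX3 9.02-fold, ZNF331 6.81-fold and ARMH1 8.12-fold. AIF1, which is also on the myeloid list, was 14.6-fold lower. The tumor cells came mostly from cluster 17, led by IL17A and IL22, and the healthy cells from clusters 12 and 18, so the class holds different clusters in the 2 libraries.

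CD8 T-like cells of the tumor sort carried chronic activation transcripts. TNFRSF9 was 30.2-fold higher (15 to 69.0), HAVCR2 31.8-fold (14.4 to 82.8), CTLA4 33.8-fold (13.4 to 110), LAYN 37.1-fold (11.4 to 191) and PDCD1 13.6-fold (7.19 to 27.6), all receptors of chronically stimulated T cells. CXCL13 was 122-fold higher (32.2 to 1027), IL17A 56.5-fold (26.4 to 144), HSPA6 12.9-fold (10.9 to 15.4) and HLA-DRA 9.36-fold (6.51 to 13.7), and SOX4 had 35 UMIs against 0, at least 48.1-fold. The 96 IL17A UMIs of the tumor sort were in 5 of 43 cells, with 41.7% of them in 1 cell, and all 7 of healthy colon were in 1 cell. Checkpoint genes were higher for 13 of 14 (median 3.70, 3.10 to 4.29), class II genes for 7 of 7 (median 1.75, 1.5 to 1.92), interferon genes for 21 of 21 (median 1.07, 0.96 to 1.58) and circulation genes for 6 of 6 (median 1.30, 0.92 to 1.61), while residency genes were split (median 0.18, -0.38 to 0.46). XCL1 was 5.99-fold lower, XCL2 4.16-fold, CD160 6.59-fold, SPRY1 6.50-fold, FOS 3.00-fold and NFKBIA 3.27-fold. TRDC, the gamma-delta receptor constant gene, had 0 UMIs in the tumor sort and 108 in healthy colon, at least 8.74-fold. Tumor gamma-delta T cells had a sort of their own, so the gates can set this ratio. The plasma cell genes IGHA1 and JCHAIN had 0 UMIs against 444 and 371, at least 35.9-fold for IGHA1, and IGLC3 had 1 against 2193. A single healthy cell held 94.8% of the IGHA1, 96.2% of the JCHAIN and 99.4% of the IGLC3 UMIs. With doublet calls kept, SPRY1 was 6.79-fold higher in the tumor sort and the circulation median was 0.09. The class held 43 tumor cells, mostly of clusters 13 and 14, and 148 healthy cells, mostly of clusters 31 and 13.

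Treg-like cells of the tumor sort (36 cells, against 32 in healthy colon) carried heat shock transcripts and more TNF, TNFSF14 and TNFSF9. HSPA6 had 469 UMIs against 0, at least 136-fold, GNLY 63 against 0, at least 18.3-fold with 74.6% of them in 1 cell, and TNFSF9 34 against 0, at least 9.86-fold. TNF was 18.0-fold higher (6.79 to 67.8), TNFSF14 24.4-fold (6.44 to 206), RHOB 16.2-fold (7.23 to 45.2), HSPA1A 6.48-fold (5.93 to 7.08), HSPA1B 6.84-fold (5.96 to 7.88) and SERPINH1 62.6-fold (10.9 to 2508). IGKC, a plasma cell gene, was 28.3-fold higher (7.52 to 238). LAG3 was 7.52-fold lower, CCR7 5.17-fold, IL6ST 4.95-fold, PELI1 5.17-fold, TENT5C 3.64-fold, ZNF331 3.23-fold, CEMIP2 3.36-fold, CD69 2.51-fold, ADTRP 3.93-fold and KDM6B 3.60-fold. Interferon genes were higher for 13 of 15 (median 1.32, 0.83 to 1.52) and stress genes for 16 of 20 (median 1.04, 0.71 to 1.32), residency genes for 4 of 9 (median -0.63, -0.99 to 0.05) and circulation genes for 3 of 6 (median 0.02, -0.49 to 0.42). ILC3-like cells (26 against 30 cells) had CXCL8 at 193 UMIs against 0, at least 73.1-fold, and IL22, the cytokine that acts on epithelium, at 62 against 0, at least 23.5-fold, each in 2 tumor cells. In these cells CCL5 was 7.22-fold lower, JAML 6.29-fold and ZFP36 2.68-fold. Each side of these ratios was 1 library, so the intervals cover counting error only and no change between patients can be tested.

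**Figure D4:**
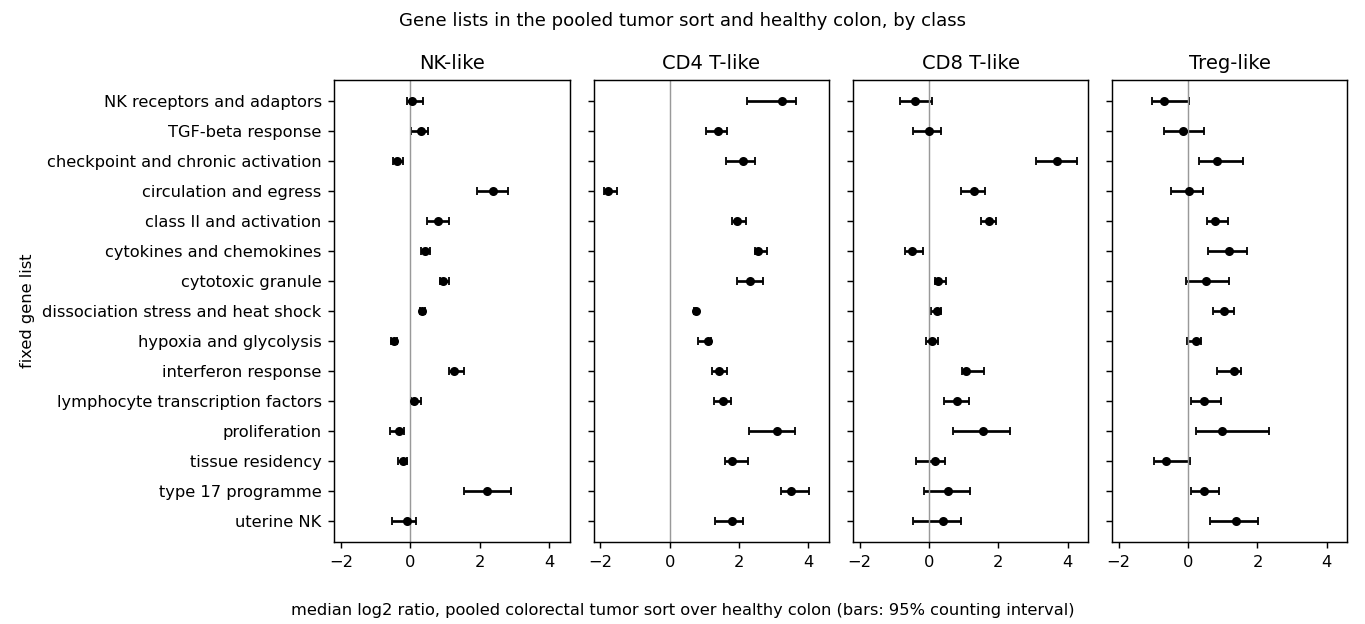
Median log2 ratio of each fixed gene list in the pooled colorectal tumor sort over healthy colon, for 4 classes. Bars are 95% intervals from counting error in 1 library per side.

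The 3 pooled colorectal sorts differed in marker genes of NK, MAIT and T cells. A TRDC UMI was found in a smaller share of the gamma-delta T sort (28.2%) than of the NK and T sort (66.3%), at unequal depth. TRDC was fixed beforehand as a marker of both NK and gamma-delta T cells. Clusters 5 and 7 held 424 and 356 of the 1005 NK-like cells of the NK and T sort. Over all their cells TRDC measured 404 and 850 CPM and CD3D 29.6 and 22.2. The 66.3% therefore does not measure gamma-delta T cells. In the MAIT sort 40.3% of cells were MAIT-like (35.4 to 45.3) and 37.8% CD4 T-like, and SLC4A10 had a UMI in 30.5% of cells (median depth 8279 UMIs) against 3.48% in the NK and T sort (7241 UMIs). SLC4A10 was 10.1-fold higher there than in the NK and T sort (7.79 to 13.3), with LAG3 at 6.36-fold, CD8A 5.28-fold, CXCL13 4.72-fold, PDCD1 4.61-fold, IL22 4.26-fold and CTLA4 3.58-fold. Type 17 genes were higher in the MAIT sort for 11 of 14 (median 1.39, 1.25 to 1.46) and cytotoxic granule genes for 0 of 13 (median -1.51, -1.61 to -1.44). The NK and T sort was 71.3% NK-like (68.9 to 73.7), with a KLRF1 UMI in 54.2% of cells against 6.80% in the MAIT sort. FCER1G measured 440 CPM in the NK and T sort and 0.27 in the MAIT sort. IGKC measured 3622 CPM in the NK and T sort, 11.6 in the MAIT sort and 0 in the gamma-delta T sort.

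The gamma-delta T sort held TRDC at 54.5-fold the level of the MAIT sort (38.5 to 79.5), with KIR2DL4 at 12.4-fold, KLRC2 at 6.23-fold and ZNF683 at 4.96-fold. KLRB1 was 11.2-fold lower, ZBTB16 42.4-fold, SLC4A10 23.5-fold, IL17A 7.88-fold and CCL20 7.05-fold, and all 14 type 17 genes were lower (median -2.48, -2.92 to -2.03). Against the NK and T sort, TRGC2 was 6.99-fold higher, and so were genes of other T cells: FOXP3 7.45-fold, RTKN2 7.30-fold, CD8B 5.17-fold, CCR7 4.05-fold, CD27 3.71-fold and CD28 4.38-fold. A TRDC UMI was found in 46 of 163 cells, 28.2% (21.5 to 35.8), at a median depth of 1581 UMIs. With at least 800 genes and at most 10% mitochondrial UMIs the share was 43.0%. TRDC was found in 1.51% of the MAIT sort, which should lack it (8279 UMIs), and 66.3% of the NK and T sort (7241 UMIs), whose NK-like clusters carried TRDC as well. These shares are at unequal depth. TRAC, the alpha-beta receptor constant gene, had a UMI in 73.0% of the cells of the gamma-delta T sort. By class 32.5% of these cells were CD4 T-like, 27.0% CD8 T-like and 14.7% Treg-like, and Scrublet removed 30 of 193 barcodes.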

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

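The tests of the residency list and of blood in colorectal tumor library 1, of other T cells and of TRGC1 or TRGC2 in the gamma-delta T sort, of the cluster with most healthy colon NK-like cells, and the list tests of the tissue difference with an estimated correlation were chosen after the results were seen.

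The tumor-healthy effect of NK-like cells differed between the tissues by the interaction test in 8 gene lists. Values are median log2 differences, endometrium minus colon, with camera's adjusted p at the preset correlation and then with an estimated correlation. Circulation and egress had -4.55 (0 of 9 genes positive, adjusted p = 4.3e-13, and adjusted p = 0.451 with an estimated correlation). Interferon response had -1.52 (4 of 22, adjusted p = 2.42e-08, and adjusted p = 0.637 with an estimated correlation). Cytotoxic granule had -2.1 (2 of 13, adjusted p = 2.42e-06, and adjusted p = 0.451 with an estimated correlation). Checkpoint had 2.11 (14 of 15, adjusted p = 2.55e-05, and adjusted p = 0.639 with an estimated correlation). Uterine NK had 2.17 (7 of 9, 1.96 without genes at 0 in an arm, adjusted p = 0.00365, and adjusted p = 0.451 with an estimated correlation). Proliferation had 1.35 (9 of 11, 1.08 without genes at 0, adjusted p = 0.00462, and adjusted p = 0.639 with an estimated correlation). Tissue residency had 0.78 (9 of 11, 0.58 without genes at 0, adjusted p = 0.0188, and adjusted p = 0.639 with an estimated correlation). TGF-beta response had 0.76 (9 of 10, adjusted p = 0.0239, and adjusted p = 0.639 with an estimated correlation).

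For the circulation genes of NK-like cells, unequal shares of FGFBP2-led clusters are argued against, since the median was -5.04 over 8 genes without these clusters. That fit kept 38 of 96 healthy endometrium cells and 138 of 157 healthy colon cells, 109 of the latter in cluster 16. It therefore does not cover a mix of the remaining clusters. The gene reference and kit of the single-patient colorectal libraries are argued against as well, with -3.52 without both libraries. The cluster that held most healthy colon cells cannot be told apart, since the median without it was -2.24 (-2.44 to -1.78 with each gene left out), on both sides of the size that would decide. Without cells that hold a CD3D, CD3E or CD3G UMI, which left 32 of 157 healthy colon cells, the median was -1.76 (0 of 9 positive, adjusted p = 0.000399, and adjusted p = 0.823 with an estimated correlation), short of the size set beforehand for arguing against these cells. Cells with CD3 transcripts in the healthy colon class, 79.6% of it, are therefore a candidate explanation for the larger part. The tissue itself stays open for the rest and was not tested apart from the patients, who differ between the tissues.

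The tumor-healthy effect of CD8 T-like cells differed between the tissues in 5 lists by the same test. Checkpoint genes had -4.21 (1 of 15 positive, -4.17 without genes at 0, adjusted p = 5.21e-20, and adjusted p = 0.908 with an estimated correlation). In healthy endometrium HAVCR2 measured 254 CPM, PDCD1 162 and CXCL13 2210, against 6.12, 11.4 and 1.75 in healthy colon. In the tumors HAVCR2 measured 234 and 55.7 CPM in the endometrial libraries and 194 in the colorectal sort. Interferon genes had -1.39 (3 of 22, adjusted p = 9.55e-14, and adjusted p = 0.908 with an estimated correlation). Class II genes had -1.59 (1 of 10, -1.69 without genes at 0, adjusted p = 4.23e-06, and adjusted p = 0.908 with an estimated correlation). B and plasma genes had 3.03 (5 of 6, 2.74 without genes at 0, adjusted p = 4.42e-05, and adjusted p = 0.908 with an estimated correlation), with JCHAIN at 324 CPM in healthy colon and 96.2% of those UMIs in 1 cell. Proliferation genes had -0.76 (3 of 11, -1.45 without genes at 0, adjusted p = 0.00859, and adjusted p = 0.908 with an estimated correlation).

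Hashtag antibodies, counted in 5 libraries and used in the comparisons only to remove doublets under an alternative, gave a signal without control samples. Exactly 1 hashtag was found on 87.9% of cells in colorectal tumor library 1 (87.0 to 88.9) and 89.4% in colorectal tumor library 2 (87.6 to 91.1). It was found on 96.1% in endometrial tumor library 1 (95.1 to 96.9), 97.8% in endometrial tumor library 2 (96.7 to 98.6) and 95.5% in the healthy endometrium pool (93.9 to 96.8).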

How the results depend on the processing

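The clustering at raised resolution for all but the shares, the removal of hashtag doublets, and the fits without both single-patient colorectal libraries were added after the data were seen; for each change below the cause was not tested. Of the 110 counts of changed genes under alternatives, 92 stayed at the reported 0 and 18 were higher. DESeq2 called 2 genes in NK-like, 2 in CD8 T-like and 100 in CD4 T-like cells between tumor and healthy, 98 between the cancers and 2 for the NK-like tissue difference. Without the low-count filter edgeR called 15 in NK-like, 49 in CD8 T-like, 559 in CD4 T-like and 23 in Treg-like cells, 723 between the cancers, and 143 and 159 for the NK-like and CD8 T-like tissue differences. Clustering each library on its own gave 8 genes in CD4 T-like cells, and at least 200 genes with at most 25% mitochondrial UMIs gave 27 between the cancers. Leaving out each library gave 0 to 20 genes in CD4 T-like cells (20 without healthy endometrium), 0 to 2 in Treg-like cells (2 without healthy colon) and 0 to 343 between the cancers (128 without endometrial tumor library 1, 343 without library 2). A lone library left in a group was assumed to vary like the other groups. The replicate numbers are those of different patients, and their deviations correlated at -0.359 over 7076 genes. With the replicate number as a block edgeR called 0 of 9646 genes between the cancers, with 936 at an unadjusted p under 0.05. With an estimated correlation camera called 0 lists in each comparison, against 2 to 12 with the preset one. Of 110 counts of lists 82 were alike, 11 higher and 17 lower. Alike includes counts that differ from the main one by a limited ratio, such as 9 and 14 lists against 12 in CD4 T-like cells.

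The NK-like share, colorectal minus endometrial, was -5.48 percentage points and -27.1 to 16.2 with a library left out, positive without colorectal tumor library 1 (16.2) and without endometrial tumor library 2 (4.72). The Treg-like share was -3.03 and ranged from -6.18 to 0.12, positive without colorectal tumor library 1. NK-like cells made up 66.9% of the NK and T sort with at least 200 genes and at most 25% mitochondrial UMIs, 67.9% at raised resolution and 68.1% without hashtag doublets. TRDC was found in 43.0% of the gamma-delta T sort with at least 800 genes and at most 10% mitochondrial UMIs, against 28.2% in the main set of cells.

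Of 550 list medians of the tumor sort over healthy colon, 463 were alike, 81 moved and 6 reversed. Circulation in NK-like cells was 1.78 with doublet calls kept, 1.61 with at least 800 genes and 3.1 with libraries clustered on their own. In CD4 T-like cells circulation was -2.3 with TMM and -1.9 with at least 800 genes, and residency 1.3 with TMM. In CD8 T-like cells with doublet calls kept circulation was 0.089 and residency 0.76. The reversed medians were NK-like proliferation at raised resolution (0.015), CD4 T-like B and plasma genes with libraries clustered on their own (-0.31), and in CD8 T-like cells cytokines (0.17) and cytotoxic genes (-0.16) with doublet calls kept and cytotoxic (-0.016) and stress genes (-0.052) with TMM.

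Of 907 values of named genes as ratios to healthy colon 4 reversed, 165 moved and 738 were alike: IGLC3 in CD8 T-like cells with libraries clustered on their own (1.22), and with doublet calls kept KLF2 (0.819) and SPRY1 (6.79) in CD8 T-like and TRDC (1.05) in NK-like cells. CXCL9 had no UMI in CD4 T-like cells with at least 200 genes and gave no value. Of 1861 log2 fold changes of named genes 12 reversed. In CD4 T-like cells between tumor and healthy these were CCL3 with doublet calls kept (-0.28) and with at least 800 genes (-0.67), and EPSTI1 (-0.0024) and PDCD1 (-0.57) with at least 200 genes. In CD8 T-like cells they were GZMK with doublet calls kept (-0.39) and with libraries clustered on their own (-0.15), and IL2RA with the latter (0.11). With each library left out, CCR7 in CD4 T-like cells ranged from -3.16 to 0.97, positive without the colorectal sort and without healthy colon (0.97 each). KLRC2 in CD8 T-like cells ranged from -2.92 to 0.199 (positive without healthy endometrium), GNLY in NK-like cells from -0.202 to 2.24 (negative without healthy colon) and CCR7 in Treg-like cells from -2.77 to 0.41 (positive without healthy colon).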

Other observations

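The tests named in the opening of the first part, TRGC1 or TRGC2 in the gamma-delta T sort, the levels of MAIT-like, ILC3-like and proliferating cells, and the shares by hashtag were chosen after the data were seen.

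MAIT-like cells carried different programmes in the libraries that held at least 20 of them and were not tested. The class was a different cluster in most of them: cluster 2 in colorectal tumor library 1 (99.9%), cluster 30 in library 2 (93.1%) and cluster 21 in endometrial tumor library 1 and the MAIT sort. CXCR6 measured 4.03 CPM in colorectal tumor library 1, 321 in colorectal tumor library 2, 186 in endometrial tumor library 1 and 350 in the MAIT sort. RGS1 measured 167, 3961, 732 and 762 CPM and GZMB 8.06, 672, 170 and 314 in the same order. SLC4A10, which marks the class, was closer, at 85.2, 65.7, 69.4 and 145 CPM. CXCL13 measured 311 CPM in the MAIT sort, 3.65 in colorectal tumor library 2 and 0 in the other libraries. CCL20 was highest in endometrial tumor library 1, at 1558 CPM against 21.3, 281 and 530. S1PR1 measured 19.0 CPM in colorectal tumor library 1 and 0 in library 2.

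Proliferating cells differed between libraries in CXCL13 and IL17A, without a test. CXCL13 measured 1837 CPM in those of endometrial tumor library 1, 1593 in healthy endometrium, 245 in colorectal tumor library 2, 98.2 in the MAIT sort and 55.2 in the NK and T sort. IL17A measured 386 CPM in the NK and T sort, 309 in the MAIT sort and 0 in healthy endometrium. ILC3-like cells had KIT at 354 CPM in the colorectal sort, CSF2 at 699 there and 169 in healthy colon, and AREG at 2049 and 1350.

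Cells by hashtag held different classes in the single-patient libraries, and the labels do not say what a hashtag marks. In colorectal tumor library 1 hashtag 3 held 92.8% MAIT-like cells and hashtag 4 58.2% NK-like cells, while hashtags 1 and 2 held 93.8% and 97.8% cells of unnamed clusters. In colorectal tumor library 2 hashtag 1 held 90.8% NK-like and hashtag 2 52.8% MAIT-like cells. In the endometrial tumors both hashtags held NK-like, CD8 T-like and CD4 T-like cells.

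Lymphocytes of colorectal tumor library 1 had naive-type and blood-type transcripts, with LEF1 at 7.66-fold, S1PR1 at 3.30-fold and RGS1 at 0.0329 of the level of library 2 over lymphocytes. NK-like cells were 569 of 4579 cells in library 1 and 681 of 1222 in library 2. Ratios over all lymphocytes therefore also carry the mix of classes, which was not tested apart. Lower depth of library 1 is argued against by the depths themselves, with medians of 1944 UMIs per cell used in library 1 and 1886 in library 2. With depths this alike, thinning could hardly have favored depth and adds no support. At 1000 UMIs per cell CD69 was found in 42.3% of lymphocytes of library 1 (40.9 to 43.8, and 61.9% at all depths) against 86.2% in library 2 (84.0 to 88.2). The gene reference and kit, which both libraries share, cannot set them apart by design, so the list ratios were no test of these. In NK-like cells the residency list had a median log2 ratio of -3.23 (-3.51 to -2.37) and the circulation list 0.24 (-0.03 to 0.50). Over lymphocytes the circulation list had 0.34 (0.15 to 0.51). Blood carried into the digest cannot be told apart, since genes of blood cells were split over whole libraries. The platelet gene PPBP was 0.112 of the level of library 2 (0.012 to 0.511) and PF4 0.0239 (0.0048 to 0.0725). The blood myeloid genes S100A8 and S100A9 were 5.87-fold and 1.75-fold higher. Of the red cell genes HBA2 was 0.485 and HBA1 1.25-fold (0.913 to 1.72), and HBB had 0 UMIs in both libraries. A sort or tissue other than that of library 2 may account for the pattern and stays open, as does a difference between the patients.

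The gamma-delta T sort held few cells with TRDC. Cells without a TRDC UMI held TRAC in 71.8% (62.7 to 79.7; median depth 1313 UMIs) and cells with one in 76.1% (61.2 to 87.4; 6640 UMIs), which decides nothing at unequal depth. TRDC missed at low depth is argued against as the whole cause, since at 1000 UMIs TRGC1 or TRGC2 was found in 10.7% (5.02 to 19.4) of cells without TRDC and 56.1% (39.8 to 71.5) of cells with it. Free RNA as the source of TRAC cannot be told apart. At 1000 UMIs TRAC was found in 48.8% of cells without TRDC (lower bound 37.7) and 24.4% of cells with it (12.4 to 40.3). The intervals of these shares overlap. TRAC was found in 11.1% of NK-like cells of the NK and T sort (9.20 to 13.2). That sort is another library, and its free RNA does not measure that of the gamma-delta T sort. Other T cells in the sort are a candidate explanation, since CD4, CD8B or FOXP3 was found in 41.0% of cells without TRDC (32.0 to 50.5) and 13.0% with it (4.94 to 26.3), and no biological explanation was tested.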
